A study of Mus musculus with 170 samples.

How the data were processed

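The counts used here were made by the authors and taken as deposited. The submitters' processing notes name Bowtie and DESeq2, with versions and settings not given, and the genome build and the role of each tool are not given in the sources used here. The labels describe TempO-Seq, a probe-based targeted assay, and also name a QuantSeq 3' library kit, so the library chemistry is stated in 2 ways. The row names of the table carry a gene symbol and a probe number, as TempO-Seq tables do. The table held 30146 probe rows for 170 samples and all columns were used. Rows of the same gene symbol were summed to 21450 symbols, of which 15160 had 1 row and 6290 had several, up to 6. The values were whole numbers with totals of 4.43 M to 8.05 M per library (median 6.59 M, ratio of largest to smallest 1.82), and were treated as raw counts.

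Samples were grouped by the labels on tissue, treatment and time into 29 groups, with 140 lung and 30 heart libraries. Each library of a tissue and time is a separate female CD-1 mouse by its title, and the hearts are from animals whose lungs were also measured, matched by the animal number. In each group every pair of libraries was checked for repeated data, and every pair differed in the counts of at least 13635 genes. The titles also give the plate, with 82 libraries on the first and 88 on the second. At 4 h all lungs were on plate 1 except 5 of pine needles smolder. At 24 h most groups had 1 library on plate 1 and the others on plate 2, all pine needles smolder lungs were on plate 1, and all hearts were on plate 2. No library was left out of the chosen analysis.

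Groups, comparisons, tests, alternatives and 34 gene lists were fixed before the data were examined. Differences were tested with edgeR 4.0.16 (quasi-likelihood F test, TMM size factors, filterByExpr) in R 4.3.3, in 1 fit of all lung libraries with group and plate terms and 1 fit of all heart libraries with group terms. P values were adjusted by Benjamini-Hochberg over the 14458 lung or 11179 heart genes of a contrast, and a gene was called under 0.05. CPM are normalised with the TMM factors. Dispersions were trended, with robust moderation of the quasi-dispersion, and a standard error is the log2 change divided by the square root of its F. Lists were tested with camera in limma 3.58.1 (preset correlation 0.01, adjusted over the lists of a contrast), with camera with an estimated correlation and with fry. Members of a list are given as called over all genes, and as called with p adjusted over the list alone. The LPS score was the mean z score of the genes that rose most under LPS, compared by exact permutation with held-out saline animals. Files were read with the data.table package, version 1.17.8.

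Genes are named by a rule. For each single smoke the 3 largest rises and 3 largest falls among called genes with a mean of at least 5 CPM in either group are named, and 8 and 8 for the LPS, mean smoke, flaming against smoldering, peat against red oak and time contrasts. Tests across several groups give the 8 smallest p. From each list up to 4 called members with the smallest p are named. Fixed markers, called or not, are Cyp1a1, Cyp1b1, Nqo1, Hmox1, Cxcl1, Il6, Saa3 and S100a8 in lung and Nppa, Nppb, Pdk4, Angptl4 and Lcn2 in heart. Any other gene is said to be chosen after its values were seen, and genes known only by a clone or model name were skipped. A few genes that the rule names are not reported here.

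Alternatives were DESeq2's size factors in edgeR, DESeq2 1.42.0 (Wald test, or likelihood ratio test across several groups), no filter beyond 1 count, each probe tested alone, no plate term, 1 plate per time, each time alone, only the compared heart groups, and leaving out each saline or LPS library. Later additions were a fit without the 6 lung libraries of fewer than 13000 detected genes, the number of detected genes as a covariate, and leaving out each exposed library of 6 comparisons. Each comparison was also repeated with limma on 100 groupings of its libraries, the real one among them.

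The tests were tested on simulated data, in which 50 genes each were changed 1.5, 2, 3 and 4 times. The changed genes were drawn from those with a mean above 5 CPM. Every gene was drawn independently, with no plate effect and no library that deviates over many genes. The shares recovered and the false calls therefore do not carry over to weaker genes or to libraries of few detected genes. For peat flame in 4 h lung edgeR recovered 2, 19, 37 and 44 of them, with 5 false among 107 calls, and limma 1, 18, 35 and 43. For LPS in 4 h lung edgeR recovered 4, 18, 35 and 42, with 4 false among 103 calls, and limma 6, 18, 35 and 43. For red oak flame in heart edgeR recovered 29, 45, 49 and 50, with 6 false among 179 calls, limma 30, 44, 49 and 50, and DESeq2 33, 45, 49 and 50, with 21 false among 198. In lung a change of 1.5 times was thus mostly missed. The recovery in heart was higher, with as many animals per group as for peat flame and a similar depth. The simulated spread came from all libraries of a tissue, in lung also those of few detected genes. What made the tissues differ was not tested.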

Results

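Gene expression was measured in the lungs and hearts of female CD-1 mice, an outbred laboratory stock, after particles from burned wildland fuels were placed in their airways. Each animal inhaled 50 µL of saline from the back of the throat, carrying particulate matter at 2 mg/mL. The 10 smokes came from 5 fuels (red oak, peat, pine needles, pine and eucalyptus), each burned in a smoldering and in a flaming phase. The controls were saline alone and bacterial endotoxin (lipopolysaccharide, LPS). The 170 libraries formed 29 groups, 24 of lung and 5 of heart. Lungs were taken at 4 h and at 24 h, from 6 animals for each smoke and for saline and from 4 animals for LPS. Hearts were taken at 24 h after saline and after both phases of red oak and peat, from 6 animals per group. Total counts per library ran from 4.43 M to 8.05 M, with a median of 6.59 M. In 6 libraries of 24 h lung, fewer than 13000 genes had a count, and the lowest were red oak flame replicate 6 with 9886 and eucalyptus flame replicate 5 with 10172. Below, a gene is called when its adjusted p in edgeR's quasi-likelihood test is under 0.05. A log2 change is given with ± its standard error, and levels, in counts scaled to library size and given per M counts (CPM), with ± SD, for n = 6 in smoke and saline groups and n = 4 for LPS.

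**Figure D1:**
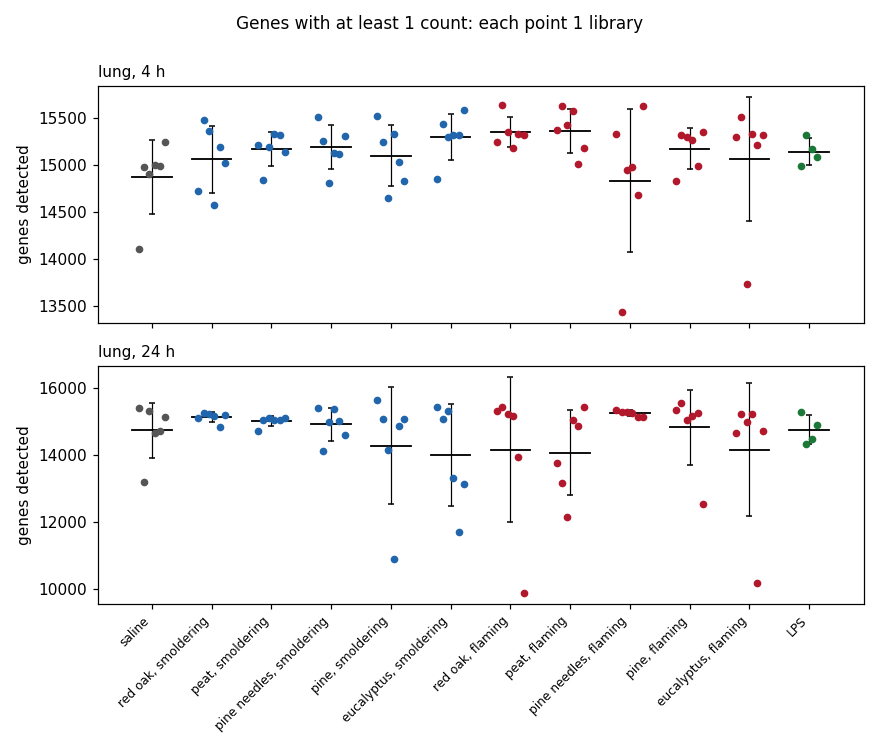
Number of genes with at least 1 count in each lung library (vertical axis, genes) by group at 4 h and 24 h (horizontal axis); points are libraries, the bar is the mean and the error bar the SD, with saline in grey, smoldering smoke in blue, flaming smoke in red and LPS in green. The 24 h groups hold the 6 libraries under 13000 genes, the lowest at 9886 in red oak flame.

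At 4 h, smoke from flaming eucalyptus raised the genes of the aryl hydrocarbon receptor, the sensor of polycyclic aromatic compounds. Cyp1a1, an enzyme that oxidises such compounds, rose by 5.51 ± 0.56 on the log2 scale, from 12 ± 10.7 CPM in saline to 546 ± 102.1 CPM, and was above every saline library in 6 of 6 animals (adjusted p = 8.41e-13). Cyp1b1, a related enzyme, rose by 2.92 ± 0.46 to 72 ± 48.8 CPM, and Nqo1, a quinone reductase under both this receptor and Nrf2, rose by 2.45 ± 0.46 to 60 ± 25.9 CPM, each in 6 of 6 (adjusted p = 3.5e-05 and 0.00216). Of the 10 receptor genes tested, 3 rose over all genes and 4 when adjusted over the list alone, and 0 fell. The list stood apart by camera with the preset correlation (adjusted p = 6.71e-07) and with an estimated correlation (adjusted p = 0.00549). The antioxidant genes of Nrf2 rose in 3 of 25 over all genes and 7 adjusted over the list alone, although the list's call was lost with an estimated correlation (adjusted p = 0.108). Txnrd1, which reduces thioredoxin, rose by 1.27 ± 0.22 and Gclm, a subunit of the glutathione-making ligase, by 0.76 ± 0.16. Tm2d2, a membrane protein, rose by 2.47 ± 0.51 to 25.8 ± 26.3 CPM. The metallothionein Mt2, which binds zinc and copper, rose by 1.70 ± 0.39 and the respiratory cytochrome Cyc1 by 0.85 ± 0.17. Fbxo11, part of a ubiquitin ligase, fell by 0.78 ± 0.18 from 627 ± 134.3 to 365 ± 30.8 CPM, below every saline library in 4 of 6. Of 17 immediate early genes, 0 rose over all genes and 6 adjusted over the list alone, with an adjusted p of 0.0429 by camera with an estimated correlation. Smoke from flaming pine raised the same enzyme, Cyp1a1, by 2.73 ± 0.50 to 79.5 ± 31.2 CPM, above every saline library in 5 of 6 (adjusted p = 0.00363). In that group 4 of the 10 receptor genes rose when adjusted over the list alone (camera with an estimated correlation, adjusted p = 0.0445). In all, 12 genes rose and 1 fell after eucalyptus flame and 1 rose after pine flame, of 14458 genes tested. The eucalyptus count was 75 without saline replicate 1, 6 without saline replicate 6, 20 without exposed replicate 1 and 4 without exposed replicate 3, and the pine count was 0 without saline replicate 1. Fitting the 4 h libraries alone gave 284 and 4 genes, and DESeq2 gave 60 and 6.

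Smoke from flaming peat raised heat shock, oxidative stress and early inflammatory genes at 4 h. Fosl1, a partner of Jun in the AP-1 transcription factor, rose by 4.48 ± 0.77 to 23.8 ± 11.8 CPM from 1.04 ± 1.24 in saline (adjusted p = 8.89e-05, above every saline library in 6 of 6). The chaperone gene Hspa1a rose by 4.23 ± 0.68 to 93.1 ± 31.4 CPM and its neighbour Hspa1b by 3.47 ± 0.70 to 155 ± 76.6 CPM. The 2 Hspa1 genes are near-identical copies, so their counts can be shared. Hmox1, which breaks down heme, rose by 3.56 ± 0.55 from 6.10 ± 2.70 to 72.3 ± 36.9 CPM in 6 of 6 animals (adjusted p = 9.9e-06). Srxn1, which repairs oxidised peroxiredoxins, rose by 2.13 ± 0.33, Txnrd1 by 1.37 ± 0.22 and Gclc, the catalytic subunit for glutathione synthesis, by 1.33 ± 0.23. In all 7 of 25 Nrf2 genes rose over all genes, 11 adjusted over the list alone and 0 fell (camera with an estimated correlation, adjusted p = 0.00145). The metallothioneins Mt2 and Mt1 rose by 3.22 ± 0.42 (400 ± 184 against 43 ± 25.7 CPM, adjusted p = 4.88e-08) and 1.80 ± 0.38. The neutrophil chemoattractants Cxcl2 and Cxcl1 rose by 3.30 ± 0.75 and 2.41 ± 0.57, and Csf2, a growth factor for granulocytes and macrophages, by 2.6 ± 0.57, each above every saline library in 5 of 6. Chemokine and cytokine genes rose in 3 of 20 over all genes and 9 adjusted over the list alone (estimated correlation, adjusted p = 0.00596). Acute phase genes rose in 3 of 16 and 8 adjusted over the list alone (estimated correlation, adjusted p = 0.000482), among them the serum amyloid gene Saa1, by 4.19 ± 1.04 to 4.31 ± 6.61 CPM. Feedback genes of NF-kB, the inflammatory transcription factor, rose in 0 of 16 over all genes and in 9 adjusted over the list alone (estimated correlation, adjusted p = 1.17e-05). Immediate early genes rose in 5 of 17, among them Atf3 by 1.74 ± 0.35, Myc by 1.61 ± 0.33 and Junb by 1.06 ± 0.23 (estimated correlation, adjusted p = 1.17e-05). The urokinase receptor Plaur rose by 1.44 ± 0.30, the amino acid response factor Atf4 by 0.49 ± 0.11 and Cyc1 by 0.70 ± 0.17. The lists of heat shock (2 of 14 rose, adjusted p = 0.0072), endothelial activation (1 of 13, adjusted p = 0.0406), glucocorticoid response (1 of 13, adjusted p = 0.00596) and cholesterol synthesis genes (0 of 17 over all genes and 3 adjusted over the list alone, adjusted p = 0.00596) also held with an estimated correlation. Osbpl6, an oxysterol-binding protein, fell by 0.98 ± 0.22 from 22.8 ± 6.26 to 11.5 ± 2.49 CPM, below every saline library in 5 of 6. Cyp1a1 did not pass, at −0.55 ± 0.48 (8.20 ± 4.33 CPM, adjusted p = 1). In all 42 genes rose and 1 fell, and leaving out any 1 saline or exposed library gave 29 to 47. The 4 h libraries alone gave 1.2e2 and DESeq2 gave 82.

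**Figure D2:**
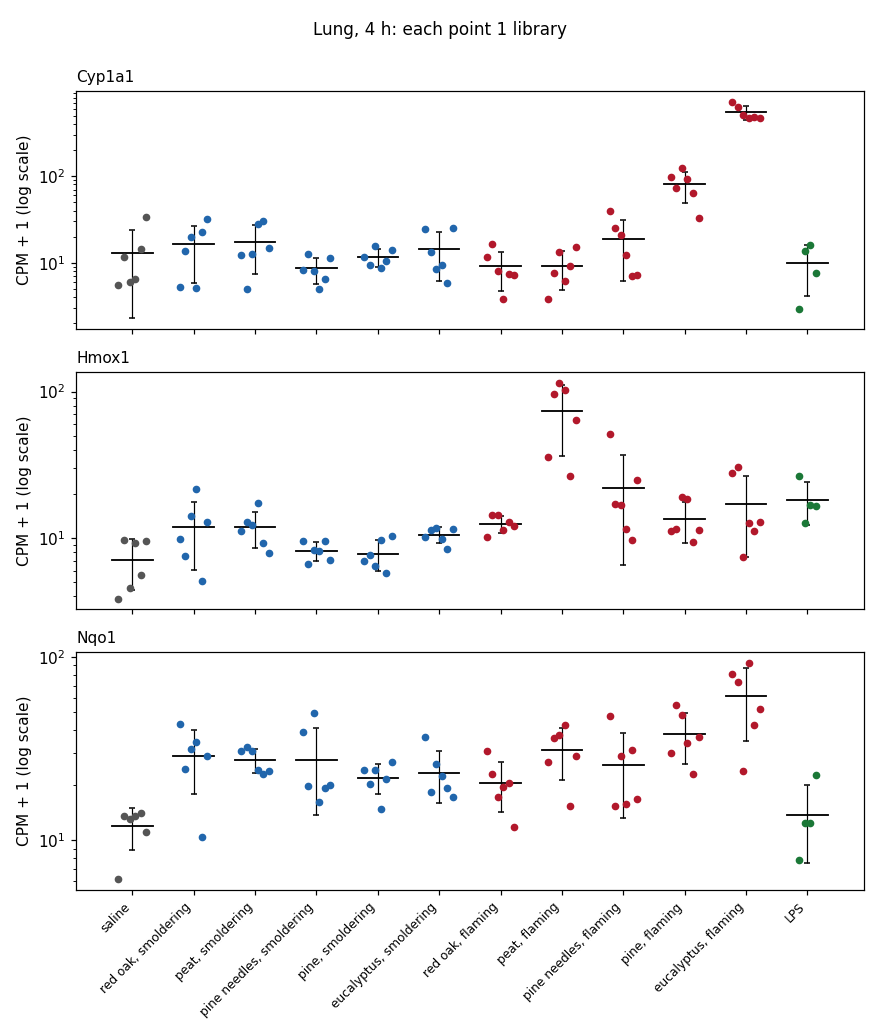
Level of Cyp1a1, Hmox1 and Nqo1 in 4 h lung (vertical axes, CPM + 1 on a log scale) for saline (grey), the 10 smokes (smoldering blue, flaming red) and LPS (green); points are libraries, the bar is the mean and the error bar the SD. Cyp1a1 averaged 546 CPM after eucalyptus flame and 79.5 after pine flame, and Hmox1 averaged 72.3 CPM after peat flame against 6.10 in saline.

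Among the other smokes at 4 h few single genes were called in the fit of all lungs. Red oak flame raised Egr1, a growth-response transcription factor, by 2.28 ± 0.36 (20.8 ± 6.05 against 4.26 ± 1.12 CPM, adjusted p = 9.3e-05) and Mt2 by 1.91 ± 0.40 (161 ± 28.8 CPM, adjusted p = 0.03), each in 6 of 6 animals. There 6 of 17 immediate early genes rose when adjusted over the list alone, and the list held with an estimated correlation (adjusted p = 2.63e-06). Pine needles flame raised Mt2 by 2.12 ± 0.40 to 187 ± 94 CPM, the farnesyltransferase subunit Fntb by 1.29 ± 0.28, the splicing protein Zranb2 by 1.18 ± 0.22 to 204 ± 59.2 CPM, and Txnrd1 by 1.03 ± 0.22. After pine needles smolder the called genes were the digestive enzyme genes Pnlip, Cela2a and Try4, chosen after their values were seen. Pnlip and Cela2a were at 0 in every saline library, and Try4 rose by 4.73 ± 0.95 to 0.627 ± 0.628 CPM. In this group 5 of 6 lungs were on plate 2 and all 4 h saline lungs on plate 1, so plate and smoke were largely confounded, and 0 genes were called without the plate term, with 4 h alone or without the filter on low counts, while the 1 gene of DESeq2 was none of these 3. Red oak smolder called 0 genes in edgeR (329 at unadjusted p under 0.05, 3 in DESeq2 and 0 in limma), but its immediate early genes stood apart with an estimated correlation (adjusted p = 0.0106, 3 of 17 adjusted over the list alone). The remaining smoldering smokes called 0 genes in edgeR and in limma: peat (259 at unadjusted p under 0.05, 1 in DESeq2), pine (436, and 1) and eucalyptus (625, and 2). Without the libraries of few detected genes eucalyptus smolder gave 7 genes, and 68 with the number of detected genes as a covariate. Peat gave 1 and 1 in these fits and pine 1 and 3. After eucalyptus smolder the list of cardiac stress genes was higher with an estimated correlation (adjusted p = 0.0148, fry adjusted p = 0.0554), with a median of 0.74 and 9 of 10 genes above 0, but 0 of 10 passed over all genes or adjusted over the list alone. By camera with the preset correlation this list was higher in 6 of 10 smokes, against the same saline lungs. Nqo1 was above every saline library in 58 of 60 smoke-exposed lungs, but its mean change of 1.36 ± 0.37 over the 10 smokes did not pass (29.6 ± 16 against 10.9 ± 3.02 CPM, adjusted p = 0.363). For the mean of all smokes 0 genes were called (763 at unadjusted p under 0.05, 8 in DESeq2 and 4 in limma), and 6 of 17 immediate early genes rose when adjusted over the list alone (estimated correlation, adjusted p = 0.00359). The number called for that mean was 16 without the libraries of few detected genes, 100 without the filter on low counts and 522 with the number of detected genes as a covariate. The count for red oak flame, 2, was 1 without saline replicate 2, 3, 5 or 6, and DESeq2 gave 11. The count for pine needles flame, 4, was 45 without saline replicate 1 and 2 without saline replicate 5 or 6, DESeq2 gave 13, the 4 h libraries alone gave 872 and the number of detected genes as a covariate gave 1212. The 3 genes of pine needles smolder were 0 without saline replicate 3 or 4. Without saline replicate 1, red oak smolder gave 1, eucalyptus smolder 4 and the mean smoke 7, and without saline replicate 4 the mean smoke gave 1.

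To ask which genes depended on the burning phase, the mean of the 5 flaming smokes was compared with that of the 5 smoldering smokes at 4 h, with 30 animals in each. Single xenobiotic, antioxidant and early response genes were higher after flaming smoke on average over the fuels, while 0 of 34 lists were called with an estimated correlation, 8 by camera with the preset correlation and 2 by fry. Cyp1a1 was higher by 1.51 ± 0.22 (131.9 ± 217 against 12.6 ± 7.82 CPM, adjusted p = 2.05e-06), with 13 of 30 flaming lungs above every smoldering one, and Cyp1b1 by 0.96 ± 0.20, the 2 of 10 receptor genes that passed over all genes (estimated correlation, adjusted p = 0.614). By group mean, Cyp1a1 was higher after flaming for eucalyptus, pine and pine needles, but lower for red oak and peat. Mt2 was higher by 1.34 ± 0.18 (198 ± 140 against 73.4 ± 28.8 CPM, adjusted p = 5.76e-08), in 20 of 30 above every smoldering lung. Fosl1 was higher by 1.6 ± 0.32, the TWEAK receptor Tnfrsf12a by 1.5 ± 0.36, Hmox1 by 1.16 ± 0.23, Hspa1a by 1.16 ± 0.28 and the mitochondrial calcium-binding protein Efhd1 by 1.24 ± 0.28. Among the smokes the mean of Hmox1 was highest after peat flame. Of the 25 Nrf2 genes 4 were higher and 1 lower, among them Osgin1, an oxidative growth inhibitor, by 0.90 ± 0.18, Srxn1 by 0.55 ± 0.15 and Txnrd1 by 0.43 ± 0.10 (estimated correlation, adjusted p = 0.636). Immediate early genes were higher in 2 of 17 over all genes and 6 adjusted over the list alone, with Atf3 at 0.65 ± 0.15. The NF-kB feedback genes were higher in 2 of 16 and 5 adjusted over the list alone, with Nfkb2 at 0.67 ± 0.18. Both lists lost their call with an estimated correlation (adjusted p = 0.14 for each). The cytokine signal suppressor Socs3 (0.69 ± 0.19), Plaur (0.57 ± 0.14), the matrix protein Thbs1 (0.56 ± 0.16), the replication helicase subunit Mcm3 (0.64 ± 0.16), the growth arrest gene Gadd45g (0.56 ± 0.15), the respiratory subunits Uqcrfs1 (0.58 ± 0.17) and Cox4i1 (0.54 ± 0.12) and the clock gene Per1 (0.61 ± 0.14) were also higher. The mitochondrially encoded transcripts mt-Nd3, mt-Atp8 and mt-Cytb were lower, at −1.15 ± 0.28, −0.99 ± 0.29 and −0.98 ± 0.27, as was Arntl, which drives the circadian clock, at −1.29 ± 0.24 (1.82 ± 0.936 against 4.43 ± 2.33 CPM). The airway markers Kcnk2 and Sntn were lower by −0.63 ± 0.16 and −0.52 ± 0.14. In all 248 genes were higher and 97 lower. By the titles, animal numbers ran in blocks, with all smoldering animals of a time before its saline animals and all flaming animals after. No label gives the order or time of sampling. Burning phase and animal order therefore cannot be told apart, also for the clock genes Per1 and Arntl. Plate 1 alone gave 43 genes, but without pine needles in either phase, since 5 of 6 animals of its smolder group were on the second plate. Fitting 4 h alone gave 1564. Among the 10 smokes 88 genes differed, with the smallest adjusted p for Cyp1a1 (2.45e-33), Zranb2 (1.54e-12), the pyrimidine-degrading enzyme Dpys (2.4e-11) and Hspa1a (5.01e-10), and 608 differed with 4 h alone. The flaming effect depended on the fuel for 3 genes in a test of that difference: Cyp1a1 (adjusted p = 3.09e-12), Tm2d2 (adjusted p = 0.00108) and Zranb2 (adjusted p = 0.0148), and DESeq2 gave 7.

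LPS at 4 h served as the known inflammatory stimulus. It raised interferon-stimulated genes in 22 of 22, with Oasl2 up by 3.56 ± 0.30 to 1126 ± 327 CPM (adjusted p = 7.88e-18), the viral restriction factor Mx1 by 5.48 ± 0.55 and Ifit2 by 4.62 ± 0.47. Cxcl10, which attracts activated T cells, rose by 8.29 ± 0.86 from 4.92 ± 3.45 to 1536 ± 976 CPM (adjusted p = 8.98e-14). Acod1, which makes itaconate in activated macrophages, rose by 8.30 ± 1.19 to 471 ± 136.99 CPM, and the granulocyte factor Csf3 by 8.22 ± 1.18 to 13.7 ± 5.03 CPM. Chemokine and cytokine genes rose in 19 of 20, among them Tnf by 4.34 ± 0.53, Cxcl1 by 5.40 ± 0.66 and Csf2 by 4.99 ± 0.64, and Il6 rose by 4.83 ± 0.81 to 76.6 ± 21.9 CPM. All 16 of 16 NF-kB feedback genes rose, such as Zc3h12a (2.47 ± 0.25), Tnfaip3 (3.34 ± 0.42) and Nfkbia (2.38 ± 0.30). Neutrophil markers rose in 17 of 20 over all genes and 19 adjusted over the list alone, with Cxcr2 at 3.43 ± 0.56, Retnlg at 2.84 ± 0.46 and S100a8 at 5.08 ± 1.0. The serum amyloid genes Saa1, Saa3 and Saa2 rose by 7.87 ± 1.14, 7.34 ± 1.23 and 6.88 ± 0.96, and acute phase genes in 10 of 16 over all genes and 15 adjusted over the list alone. Slfn4, a myeloid interferon-induced gene, rose by 6.46 ± 0.64 to 2333 ± 1671 CPM. Adhesion genes of activated endothelium rose in 9 of 13, among them Vcam1 by 2.18 ± 0.25, Selp by 4.18 ± 0.51 and Icam1 by 2.45 ± 0.34. Immediate early genes rose in 8 of 17, p53 targets in 7 of 16, ATF4 stress genes in 5 of 16 and glucocorticoid response genes in 4 of 13. These 10 lists held with an estimated correlation, the largest adjusted p being 0.041 for the glucocorticoid list. The largest falls were of Crb1, a polarity protein, by −3.34 ± 0.45, and Gdf10, a growth factor of the BMP family, by −2.96 ± 0.48 (5.87 ± 3.80 against 46.2 ± 20.7 CPM). The airway genes Cckar (−2.17 ± 0.39), Kcnk2 (−1.82 ± 0.41) and Tppp3 (−0.71 ± 0.19) fell, as did the B cell gene Cd79a (−1.57 ± 0.41), each below every saline library in 4 of 4. Of the Nrf2 genes 6 of 25 rose and 1 fell (estimated correlation, adjusted p = 0.431), and Cyp1a1 did not pass (−0.41 ± 0.54, adjusted p = 0.762). In all 793 genes rose and 505 fell, with 915 to 1322 called when any 1 saline or LPS library was left out. The 4 h libraries alone gave 2416.

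At 24 h flaming peat raised acute phase genes in the lung. Timp1, an inhibitor of matrix proteases, rose by 3.10 ± 0.37 from 25 ± 5.42 to 215 ± 145 CPM, in 6 of 6 animals (adjusted p = 1.63e-09). The serum amyloid genes Saa3 and Saa1 rose by 4.94 ± 1.11 to 82.1 ± 103.3 CPM (5 of 6, adjusted p = 0.0314) and 4.70 ± 1.01 to 9.34 ± 11.1 CPM (3 of 6). Their relative Saa2, at 0 in every saline library, was at 1.52 ± 1.43 CPM. Saa1 and Saa2 are near-identical, so their counts can be shared. Ly6i, a monocyte surface protein, rose by 3.97 ± 0.73 to 21 ± 13.3 CPM, and Ccl7, which recruits monocytes, by 3.12 ± 0.67 to 9.99 ± 7.66 CPM, each in 6 of 6. The other called genes, Slfn4, the T cell costimulatory receptor Tnfrsf9, Zranb2 and the primase Prim1, were chosen after their values were seen. Slfn4 rose by 2.62 ± 0.53 to 72.4 ± 65 CPM, Tnfrsf9 by 3.31 ± 0.74 to 41 ± 34 CPM, Zranb2 by 1.04 and Prim1 by 0.98. Acute phase genes rose in 4 of 16 over all genes and 10 adjusted over the list alone (estimated correlation, adjusted p = 0.00181), and chemokine genes in 1 of 20 and 9 adjusted over the list alone (estimated correlation, adjusted p = 0.434). Hmox1 and Cxcl1, which had risen at 4 h, did not pass at 24 h, at −0.06 ± 0.53 and 1.85 ± 0.59. Whether the effect of peat flame differed between the times was not tested. Eucalyptus flame raised Timp1 by 1.82 ± 0.36 to 87.2 ± 85.2 CPM, in 5 of 6 (adjusted p = 0.0202). Red oak smolder raised Marco, a macrophage scavenger receptor, by 4.21 ± 0.86 to 12 ± 9.24 from 0.614 ± 0.694 CPM, in 5 of 6 (adjusted p = 0.0453). Peat smolder raised Zranb2 by 1.08 ± 0.22 to 215 ± 30.5 from 102.7 ± 33.2 CPM, in 6 of 6. Pine needles smolder raised Zranb2 by 1.33 ± 0.24 and the ubiquitin-like gene Ubd by 5.36 ± 1.02 to 9.67 ± 20.3 CPM (3 of 6), and lowered Pgm5, a muscle adhesion protein, by −1.24 ± 0.26. Pine needles flame lowered Adm, the vasodilator adrenomedullin, by −1.72 ± 0.35 from 134.1 ± 30.1 to 40.7 ± 17.5 CPM, below every saline library in 6 of 6 (adjusted p = 0.0363). In edgeR 0 genes were called after pine smolder (352 at unadjusted p under 0.05, 1 in DESeq2, 4 in limma), eucalyptus smolder (745, 0 and 0) and pine flame (329, 2 and 0). The mean smoke called 1 gene, Csprs, chosen after its values were seen, at −4.41 ± 0.81 and 0.201 ± 0.488 CPM, against 0 in DESeq2.

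These small 24 h counts turned on single libraries. The 10 genes of peat flame were 4, 5, 3 and 6 without saline replicate 1, 3, 4 and 5. The 1 gene of eucalyptus flame, Timp1, was 0 without saline replicate 1, 3, 4 or 6, 3 without replicate 2 and 2 without replicate 5. The Marco count was 0 without saline replicate 1, 2, 3, 5 or 6, that of Zranb2 after peat smolder was 0 without saline replicate 1, 3, 4 or 6, and the 3 genes of pine needles smolder were 0 without saline replicate 1. The Adm count was 0 without saline replicate 2, 3, 4 or 5, and the Csprs count was 2 without saline replicate 1 and 0 without replicate 6. Without the 6 libraries of few detected genes, peat flame gave 14 genes, eucalyptus flame 11, red oak smolder 3 and pine needles flame 1351. With 24 h alone peat flame gave 3 genes, pine needles smolder gave 1, and eucalyptus flame, red oak smolder, peat smolder and pine needles flame gave 0.

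**Figure D3:**
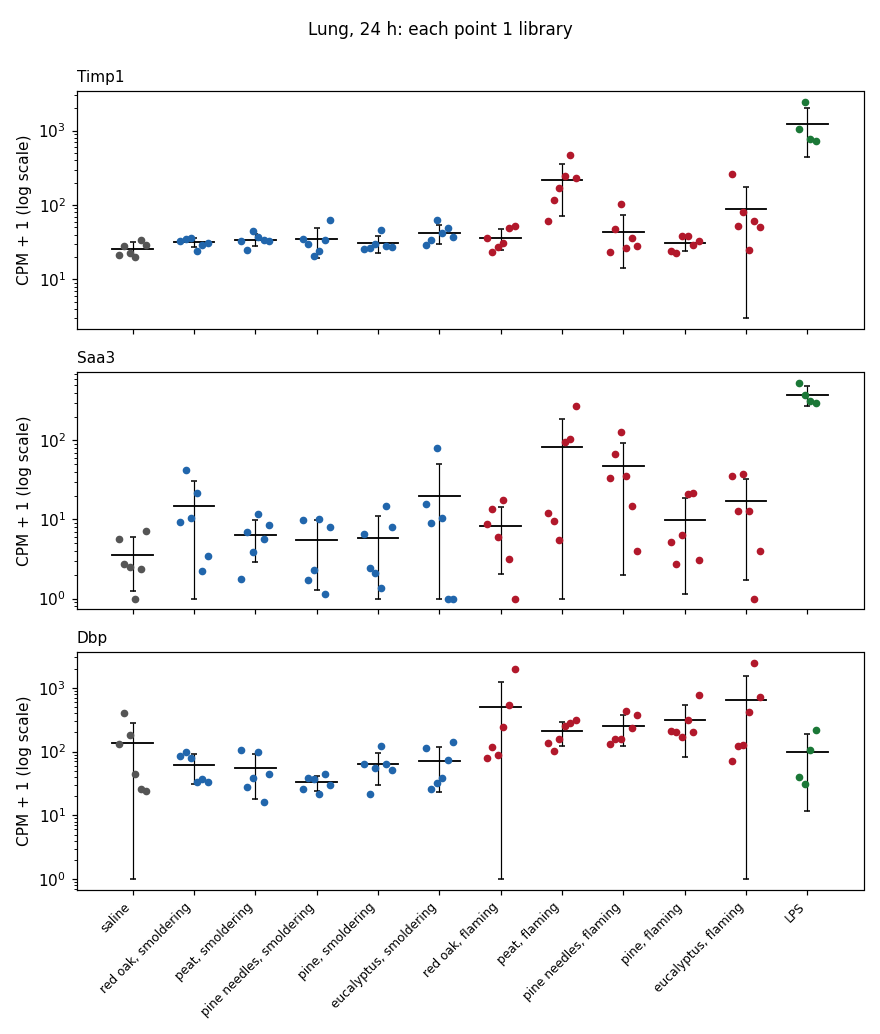
Level of Timp1, Saa3 and Dbp in 24 h lung (vertical axes, CPM + 1 on a log scale) for saline (grey), the 10 smokes (smoldering blue, flaming red) and LPS (green); points are libraries, the bar is the mean and the error bar the SD. Timp1 averaged 215 CPM after peat flame against 25 in saline, and Dbp averaged 384 CPM over the flaming and 55.7 over the smoldering groups.

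Between flaming and smoldering smoke at 24 h 16 genes differed, 6 of them genes of the circadian clock. Dbp, an output factor of the clock, was higher after flaming smoke by 2.66 ± 0.28 (384 ± 529 against 55.7 ± 34 CPM, adjusted p = 3.09e-12), with 21 of 30 flaming lungs above every smoldering one. The clock repressors Nr1d1 and Nr1d2 were higher by 1.80 ± 0.26 and 0.92 ± 0.14, while the activators Arntl and Npas2 were lower by −1.24 ± 0.22 and −2.05 ± 0.33, and Nfil3, which opposes Dbp, by −0.66 ± 0.12. Of 18 clock genes 3 were higher and 3 lower over all genes, and 4 and 4 adjusted over the list alone. Saline lungs held Dbp at 133.8 ± 145 CPM. Timp1 was higher by 0.86 ± 0.16 and the tetraspanin Tspan4 by 0.69 ± 0.11. Adm (−0.87 ± 0.15), the sorting nexin Snx22 (−0.79 ± 0.19), Fam124b (−0.78 ± 0.16), the cell cycle inhibitor Cdkn1a (−0.68 ± 0.16), the glycogen regulator Ppp1r3c (−0.63 ± 0.12), Lonrf3 (−0.54 ± 0.12) and the chaperone Hspa8 (−0.52 ± 0.10) were lower. Acute phase genes were higher in 1 of 16 and 6 adjusted over the list alone (estimated correlation, adjusted p = 0.0133). In all 5 genes were higher and 11 lower, and DESeq2 called 38. Without the 6 libraries of few detected genes there were 44.

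The calls after red oak flame at 24 h depended on 1 lung. Of its 253 called genes 225 rose, led by the zinc finger gene Zfp980 (3.79 ± 1.08, 9.92 ± 23.4 CPM), the antiplasmin gene Serpinf2 (3.76 ± 0.77, 22.7 ± 52 CPM) and the ribosomal protein gene Rps19 (3.40 ± 0.76, 41987 ± 95998 against 3848 ± 3880 CPM), and these were above every saline lung in 1, 2 and 1 of 6 animals. Birc3, an apoptosis inhibitor (1.34 ± 0.31), and Slc34a2, the phosphate transporter of alveolar type 2 cells (0.82 ± 0.20), were each above every saline lung in 1 of 6. Among the 28 that fell, Aldh1b1, a mitochondrial aldehyde dehydrogenase (−1.68 ± 0.48, 4.64 ± 3.03 against 15.9 ± 6.02 CPM), and the riboflavin transporter Slc52a3 (−1.25 ± 0.35) were below every saline lung in 5 and 6 of 6 animals. The transcription factor Snai1 (−1.31 ± 0.35), Nfil3 (−0.90 ± 0.26) and the fatty acid oxidation gene Hadha (−0.56 ± 0.16) were so in 3, 4 and 2. Without exposed replicate 6, the library with 9886 detected genes, 0 genes were called in edgeR (1726 at unadjusted p under 0.05 with it). The median change of the 225 that rose went from 1.58 to −0.08 without it, and that of the 28 that fell, in the direction called, from 0.75 to 0.63, with 28 of 28 still lower. Without another exposed library the count was 392 (replicate 1), 407 (2), 416 (3), 397 (4) and 459 (5), and without saline replicate 1, 2 or 4 it was 148, 444 and 130, while without saline replicate 3 there were 98 that rose and 3 that fell. The tests across smokes held the same libraries. Between the 10 smokes 2607 genes differed at 24 h, with the smallest adjusted p for Timp1 (1.99e-15), Zranb2 (9.75e-14), the splicing factor Hnrnph1 (6.47e-10) and Dbp (6.47e-10), and 90 with 24 h alone. The flaming effect depended on the fuel for 1888 genes, among them Ubd, the thyroid hormone receptor Thra and Hnrnph1 (adjusted p = 0.000468 for each), but for 2 genes without the 6 libraries of few detected genes and 0 with 24 h alone.

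LPS at 24 h kept inflammatory genes high and lowered airway and muscle genes, and its changes are relative to a median of −0.12 over all genes. Interferon-stimulated genes rose in 22 of 22, with Gbp2, a guanylate-binding protein against intracellular pathogens, up by 5.08 ± 0.38 to 9738 ± 2985 CPM, Oasl2 by 4.27 ± 0.31 and Irf7 by 4.96 ± 0.45. Acod1 rose by 10.7 ± 1.29 to 2353 ± 1486 CPM, Ubd by 10.2 ± 1.06, Cxcl10 by 9.50 ± 0.91, Cxcl9 by 7.96 ± 1.07, Slfn4 by 7.85 ± 0.68 and Ccl7 by 7.91 ± 0.80. Timp1 rose by 5.63 ± 0.43 to 1236 ± 794 CPM (adjusted p = 9.89e-22). Chemokine genes rose in 18 of 20, among them Tnf (6.01 ± 0.56) and Ccl2 (7.24 ± 0.86), NF-kB feedback genes in 15 of 16, and acute phase genes in 13 of 16. Neutrophil markers rose in 16 of 20, such as Ly6g (3.69 ± 0.32, 1256 ± 274 against 97.5 ± 32.9 CPM) and Clec4e (6.07 ± 0.64). Markers of recruited monocytes rose in 10 of 16, such as Plac8 (3.50 ± 0.33) and Ly6c2 (4.41 ± 0.49), and Marco rose by 4.39 ± 0.91. ATF4 stress genes rose in 7 of 16, with Atf3 at 3.59 ± 0.38. These 7 lists held with an estimated correlation, the largest adjusted p being 0.00816 for the monocyte list. The airway secretory genes fell in 7 of 12 and rose in 1, with the secretoglobin Scgb3a2 at −3.04 ± 0.41 (145 ± 47.3 against 1195 ± 543 CPM) and the club cell enzyme Cyp2f2 at −2.13 ± 0.38. Ciliated cell genes fell in 4 of 14, with Tppp3 at −1.58 ± 0.20. These lists lost their call with an estimated correlation (adjusted p = 0.106 and 0.11). Cyp1a1 fell by −4.88 ± 0.84 to 0.272 ± 0.225 CPM, Pck1, a gluconeogenic enzyme, by −7.19 ± 1.66, the goblet cell gene Clca1 by −4.91 ± 1.72 and the endothelial von Willebrand factor gene Vwf by −1.0 ± 0.24, each in 4 of 4. Markers of heart muscle, which lines the pulmonary veins of mice, fell in 6 of 15, with Myl7 at −2.99 ± 0.83 and Tnni3 at −2.24 ± 0.61 (estimated correlation, adjusted p = 0.11). In all 1096 genes rose and 652 fell, and 986 were called without LPS replicate 2. With 24 h alone there were 1142.

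Differences between the times were tested directly. The LPS effect at 24 h was larger than at 4 h for Nos2, the inducible nitric oxide synthase, by 4.97 ± 0.67 (adjusted p = 1.04e-07), the macrophage receptor Slamf8 (5.29 ± 1.07), Ubd (5.93 ± 1.46), the creatine-making enzyme Gatm (3.46 ± 0.59), Aif1, a macrophage actin-binding protein (3.13 ± 0.67), the MHC class II activator Ciita (3.03 ± 0.80), Arg1 (2.75 ± 0.60), Timp1 (2.44 ± 0.55), Ly6g (1.90 ± 0.44) and Gbp2 (1.90 ± 0.50). It was lower for Cyp1a1 (−4.47 ± 1.0), the choline phosphodiesterase Enpp6 (−2.96 ± 0.58), Scgb3a2 (−2.26 ± 0.51), Gclc (−1.62 ± 0.36) and Vwf (−1.22 ± 0.33). In all 63 genes were higher and 21 lower, with 19 without 24 h LPS replicate 2, 44 on 1 plate per time and 236 without the libraries of few detected genes. The mean smoke effect differed between the times for 0 genes in edgeR (632 at unadjusted p under 0.05, 1 in DESeq2, 0 in limma). Cyp1a1 was at −1.05 ± 0.51, Cyp1b1 at −1.16 ± 0.47 and Hmox1 at −1.15 ± 0.56 (adjusted p = 1 for each). Saline lungs differed between the times for 0 genes in edgeR (1031 at unadjusted p under 0.05, 10 in DESeq2, 0 in limma), and for 7 and 12 without 24 h saline replicate 5 and 6. All 6 saline lungs at 4 h were on plate 1 and 5 of 6 at 24 h on plate 2, so this comparison leaned on the plate term. It gave 8 genes without that term, 45 without the libraries of few detected genes and 635 with the number of detected genes as a covariate. A score of the 100 genes that rose most under LPS against saline replicates 1 to 3 was compared in each smoke group with the other saline animals by exact permutation of 6 against 3. The smallest p that this test can give is 0.0119, which is 0.238 when adjusted over 20 groups for a group that differs alone, so it could not show whether single groups differed. The mean score was above saline in 12 of the 20 groups, and in 17 with the saline animals exchanged. After peat flame at 4 h it was higher by 0.21, above each of the other saline lungs in 2 of 6 animals (exact permutation p = 0.464), and with the saline animals exchanged by 0.67, in 6 of 6 (exact permutation p = 0.0238).

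In the heart at 24 h, smoke from flaming red oak raised connective tissue and vessel genes and lowered respiratory chain genes. Col1a1, the main fibrillar collagen chain, rose by 1.87 ± 0.41 from 94.1 ± 38.6 to 345 ± 147 CPM, in 6 of 6 animals (adjusted p = 0.00574). Fibroblast and matrix genes rose in 10 of 13 over all genes and 11 adjusted over the list alone, among them the growth factor receptor Pdgfra (1.02 ± 0.18, adjusted p = 0.00159), the thrombospondin Thbs2 (0.99 ± 0.25) and Tnc (2.30 ± 0.60). Pamr1, a muscle regeneration-linked secreted protein, rose by 2.09 ± 0.53 and the neuropeptide receptor Npy1r by 2.24 ± 0.74. Endothelial genes rose in 6 of 15 and fell in 1, with the growth factor receptors Kdr (0.71 ± 0.14), Tek (0.71 ± 0.15) and Tie1 (0.76 ± 0.18) and the anticoagulant Thbd (0.57 ± 0.12). Immediate early genes rose in 6 of 13, with Fos at 1.75 ± 0.51, Egr1 at 1.37 ± 0.37 and Junb at 0.78 ± 0.18. The macrophage complement genes C1qb and C1qc rose by 0.64 ± 0.22 and 0.53 ± 0.18, the pentose phosphate enzyme G6pdx by 1.06 ± 0.20 and Errfi1, a brake on growth factor receptors, by 0.97 ± 0.22. Respiratory chain genes fell in 8 of 18 over all genes and 11 adjusted over the list alone, with Cox4i1 at −0.73 ± 0.15 (487 ± 81.7 against 806 ± 199 CPM), cytochrome c, Cycs, at −0.59 ± 0.14 and Ndufb5 at −0.51 ± 0.12. The ventricular myosin light chains Myl2 and Myl3 fell by 0.66 ± 0.16 (5779 ± 1369 against 9121 ± 1409 CPM) and 0.61 ± 0.17, each below every saline heart in 5 of 6, but these were the 2 of 16 heart muscle markers that fell over all genes (4 fell and 1 rose adjusted over the list alone, estimated correlation, adjusted p = 0.244). The fatty acid binding protein Fabp3 fell by 0.46 ± 0.14. The ribosomal gene Rps14 fell by 1.17 ± 0.26 and the histone gene Hist1h1b by 1.61 ± 0.51. The fibroblast, endothelial, immediate early and respiratory lists were called by camera with the preset correlation and lost the call with an estimated correlation (adjusted p = 0.244 for each). With the preset correlation respiratory genes were lower in 4 of 4 smokes, and the fibroblast, endothelial and immediate early lists each higher in 3 of 4. All 4 smokes shared the same 6 saline hearts, so part of this pattern may come from the saline hearts. Of 11179 genes 596 rose and 748 fell. The count was 670, 805 and 846 without saline replicate 1, 2 and 4, and 644 without exposed replicate 2. With the number of detected genes as a covariate it was 3, and the median change of the called genes, in the direction called, went from 0.61 to 0.33.

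Smoldering peat raised single connective tissue genes in the heart, against the same 6 saline hearts, and whether it shared its genes with red oak flame was not tested. Col1a1 rose by 1.57 ± 0.40 to 280 ± 144 CPM (adjusted p = 0.03), periostin, Postn, by 1.43 ± 0.42 to 214 ± 87.7 CPM, Pamr1 by 1.95 ± 0.53, the protease inhibitor Timp3 by 0.82 ± 0.21 and Pdgfra by 0.91 ± 0.18. Fibroblast genes rose in 4 of 13 over all genes and 11 adjusted over the list alone (estimated correlation, adjusted p = 0.4). Errfi1 rose by 1.25 ± 0.22 (76 ± 24.3 against 31.8 ± 9.47 CPM), Kdr by 0.67 ± 0.14, the endothelial cadherin Cdh5 by 0.56 ± 0.15 and Thbd by 0.61 ± 0.12. Of the 15 endothelial genes 2 rose and 1 fell over all genes, and 6 and 2 adjusted over the list alone (estimated correlation, adjusted p = 0.4). The interferon-inducible GTPase Gvin1 rose by 1.79 ± 0.52 to 6.83 ± 4.92 CPM, and Cdkn1a by 1.15 ± 0.30. Myl2 fell by 0.65 ± 0.16 and the muscle LIM protein Csrp3 by 0.64 ± 0.15 (3669 ± 542 against 5726 ± 965 CPM), each below every saline heart in 5 of 6. Respiratory chain genes fell in 2 of 18 over all genes and 6 adjusted over the list alone, among them Cox4i1 (−0.60 ± 0.15) and Cox6c (−0.60 ± 0.16), with an adjusted p of 0.4 for the list with an estimated correlation. The mitochondrial peptidase Immp2l fell by 1.19 ± 0.26. In all 267 genes rose and 213 fell. The count was 190, 189 and 197 without saline replicate 1, 2 and 4, and 222, 141, 176 and 279 without exposed replicate 1, 3, 4 and 6. DESeq2 gave 757, and with the number of detected genes as a covariate there were 0.

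**Figure D4:**
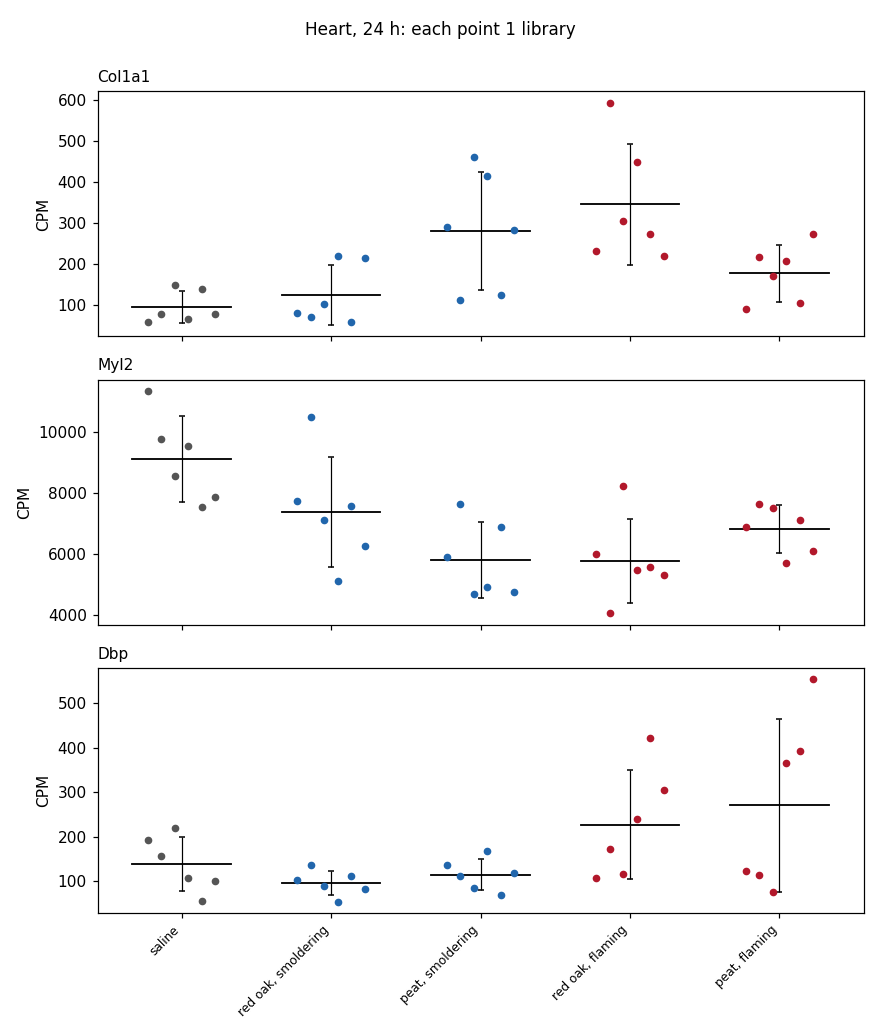
Level of Col1a1, Myl2 and Dbp in 24 h heart (vertical axes, CPM on a linear scale) for saline (grey), red oak and peat smolder (blue) and red oak and peat flame (red); points are libraries, the bar is the mean and the error bar the SD. Col1a1 averaged 345 CPM after red oak flame, 280 after peat smolder and 94.1 in saline, and Myl2 averaged 5779, 5814 and 9121 CPM.

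The other heart comparisons called few genes. Peat flame raised Jag1, a Notch ligand, by 0.94 ± 0.18 (11.5 ± 2.13 against 6.02 ± 0.767 CPM, adjusted p = 0.0475), the antiproliferative gene Btg2 by 0.87 ± 0.15 (51.6 ± 9.65 against 28.2 ± 5.86 CPM, adjusted p = 0.0329) and Klf2, which responds to blood flow, by 0.80 ± 0.16, each in 6 of 6 animals. It also raised Dock10, chosen after its values were seen, by 0.73, and lowered the histone gene Hist1h2bk by −1.09 ± 0.22. Its immediate early genes rose in 0 of 13 over all genes and 6 adjusted over the list alone (estimated correlation, adjusted p = 0.276), and its proliferation genes fell in 9 of 19 adjusted over the list alone (estimated correlation, adjusted p = 0.286). The 5 genes were 2 without saline replicate 1 or 4, and 0 without saline replicate 2 or 5, and DESeq2 gave 38. Red oak smolder called 0 genes in edgeR (700 at unadjusted p under 0.05, 0 in DESeq2 and 0 in limma). There the genes of red blood cells were higher in 8 of 9 when adjusted over the list alone, with a median of 1.51 (estimated correlation, adjusted p = 0.353). Between flaming and smoldering smoke, with 12 hearts each, the homeobox gene Hlx (0.63 ± 0.12) and the selenium-binding protein Selenbp2 (0.62 ± 0.11) were higher after flaming, and the histone genes Hist1h2bb (−0.99 ± 0.18) and Hist1h2bk (−0.82 ± 0.15) were lower. DESeq2 gave 93 genes there. Clock genes were higher in 6 and lower in 1 of 17 adjusted over the list alone, and proliferation genes lower in 12 of 19 (estimated correlation, adjusted p = 0.328 for each). Between peat and red oak 0 genes differed in edgeR (322 at unadjusted p under 0.05, 0 in DESeq2 and 0 in limma). The fixed markers Nppa, Nppb, Pdk4, Angptl4 and Lcn2 did not pass in any heart comparison. The natriuretic peptide gene Nppa was at 1.65 ± 0.79 after red oak flame (289 ± 362 against 92.2 ± 26.3 CPM, adjusted p = 0.175), Nppb at −0.86 ± 0.47, the metabolic regulators Pdk4 at −0.60 ± 0.30 and Angptl4 at −1.20 ± 0.80. The acute phase protein gene Lcn2 was at 1.09 ± 0.28 after peat flame (18.8 ± 7.16 against 8.80 ± 3.21 CPM, adjusted p = 0.165).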

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

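The tests that weigh explanations in this part were all chosen only after the results were seen. A library was set apart where its gap to the nearest other library of its group was too large a share of the group's range. This was so for 33 of 275 sets of marker levels and numbers of detected genes, and chance sets apart about 1 in 20 groups.

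The number of detected genes was far from the rest (nearest other in brackets) in red oak flame replicate 6 at 9886 (13948), eucalyptus flame replicate 5 at 10172 (14653), pine smolder replicate 4 at 10886 (14136), pine flame replicate 6 at 12545 (15050), saline replicate 2 at 13196 (14657), peat smolder replicate 1 at 14710 (15036) and red oak smolder replicate 5 at 14827 (15104), all in 24 h lung. In 4 h lung it was so for eucalyptus flame replicate 3 at 13734 (15218), saline replicate 1 at 14108 (14906) and red oak flame replicate 2 at 15644 (15353), and in heart for peat smolder replicate 4 at 13949 (13728).

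Marker genes were far from the rest mostly in the same libraries. In 24 h lung Nqo1 was at 0 CPM in pine smolder replicate 4 (4.72), saline replicate 2 (3.44) and eucalyptus flame replicate 5 (5.90), and at 0.720 in red oak flame replicate 6 (10.5). Cxcl1 was at 0 in pine smolder replicate 4 (1.99), saline replicate 2 (1.77) and eucalyptus smolder replicate 5 (2.88). Il6 was at 0 in red oak smolder replicate 5 (0.919), red oak flame replicate 6 (1.17) and pine flame replicate 6 (0.620). Hmox1 was at 0 in pine needles smolder replicate 2 (4.08) and pine smolder replicate 4 (2.88), and at 1.41 in pine needles flame replicate 6 (5.40). Cyp1a1 was at 0.550 in red oak smolder replicate 5 (6.23), and Cyp1b1 at 2.92 in pine smolder replicate 6 (6.62). In 4 h lung Nqo1 was at 5.16 in saline replicate 1 (10.1), Cyp1b1 at 26.2 in pine smolder replicate 6 (9.18), Il6 at 12.4 in pine smolder replicate 2 (2.22), Cxcl1 at 1.62 in eucalyptus smolder replicate 5 (7.57) and S100a8 at 5.25 in eucalyptus flame replicate 2 (1.39). In heart Nppa was at 1026 CPM in red oak flame replicate 2 (183) and Angptl4 at 0 in peat flame replicate 2 (8.80).

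Effects that differed between groups by a test of the difference were the dependence of the flaming effect on fuel, for 3 genes in 4 h lung and 1888 in 24 h lung, and the LPS effect between the times, for 84 genes. The 1888 became 2 without the libraries of few detected genes, 4 with the number of detected genes as a covariate and 0 with 24 h alone.

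For the 24 h red oak flame lungs, with Rps19, Serpinf2 and Birc3 among the 253 called genes, 1 library of few detected genes fits as the source of the 225 that rose. Without replicate 6 there were 0 called genes. The median change of those 225 went from 1.58 to −0.0812 without it, with median standard errors of 0.38 and 0.31, so a response of that size shared by the other animals is excluded for them as a set, although 10 of 225 were still higher at an unadjusted p under 0.05. The 28 that fell were still lower in 28 of 28, with a median change, in the direction called, of 0.748 with replicate 6 and 0.629 without it (median standard errors 0.21 and 0.21). The falls were thus also present in the other animals. Because the 28 genes were chosen with those same animals, replicate 6 as the source of their calls cannot be excluded. Their calls ended although their unadjusted p without it, 0.000346 to 0.0106, began below the 0.00086 that had passed, since fewer small p over all genes made the adjustment stricter (smallest adjusted p = 0.742). Whether the falls are a response to smoke stays open, because 0 were called without replicate 6 and the genes were chosen with the same animals. The score of the 253 genes was 3.72 above saline in replicate 6 and between −0.18 and 0.39 in the others.

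For the hearts after red oak flame, with Col1a1 up and Myl2 down, the number of detected genes may carry part of the difference. Within groups it ran with the score of the called genes (r = 0.758, permutation p = 1e-05, the smallest the permutations can give, rho = 0.723, r without the 2 farthest 0.695, n = 30, 1 correlation tested). With detected genes as a covariate the score difference went from 0.65 ± 0.10 to 0.38 ± 0.08, so 57.7 percent was left, and the test cannot tell library quality from biology. The mean number of detected genes was 13822.8 after red oak flame, 13727.5 after peat smolder, 13651.3 after peat flame, 13559.3 after red oak smolder and 13376.2 in saline. The called genes of the 4 smokes, 1344, 480, 5 and 0, ran in the same order. A lower share of cardiomyocytes alone would raise all other cell types alike. Fibroblast genes were higher by 0.99 ± 0.21, macrophage genes by 0.64 ± 0.22 and endothelial genes by 0.25 ± 0.06. The highest and lowest of these were 3.86 standard errors apart, and cardiomyocyte markers were at −0.06 ± 0.10, which argues against it. It is not excluded, because that pair was picked by its values in the same hearts and the scores were not adjusted for detected genes.

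For the clock genes Dbp, Nr1d1 and Arntl in 24 h lung, animals sampled at different times of day would make lung and heart run together. This fits for Dbp and Nr1d1 within groups and is left open for Arntl. Any other influence on the whole animal would give the same relation, and no label gives the time of day. The relation within groups therefore cannot tell what made flaming differ from smoldering. Animal numbers also ran in blocks by burning phase, so phase and animal order cannot be told apart. Within groups Dbp in lung ran with Dbp in the heart of the same animal (r = 0.711, permutation p = 4e-05, rho = 0.793, r without the 2 farthest 0.774, adjusted p = 0.00012 over a family of 3, 30 animals), as did Nr1d1 (r = 0.629, rho = 0.633, r without the 2 farthest 0.613, adjusted p = 0.00141). For Arntl the relation did not pass (r = 0.311, rho = 0.284, r without the 2 farthest 0.234, adjusted p = 0.0997). Between flaming and smoldering, Dbp differed by 2.13 in lung and 1.02 in heart of the same 24 animals. Unscaled, the lung exceeded the heart by 1.11 (permutation p = 0.00088), but within groups Dbp also varied 1.67 times as much in lung as in heart, and with heart scaled to the spread in lung the excess was 0.43 (permutation p = 0.285). An added effect in the lung itself thus stays open, and the answer depends on that scaling.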

How the results depend on the processing

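Every number of called genes was recomputed with other choices, and below a value under another choice is followed in brackets by that of the chosen analysis wherever the 2 differed by more than 1.5 times. The fit without the lung libraries of few detected genes, the covariate of detected genes and the leaving out of exposed libraries were chosen after the results were seen, and the other choices before. Of 2309 comparisons of named genes under other size factors, DESeq2, no plate term or 1 plate per time, 2198 stayed called or stayed uncalled, 3 gained a call and 0 reversed. A reversal was counted only for a gene called under the chosen analysis or the other choice. The direction of genes called under neither was not compared. Direction did not hold in red oak flame lung at 24 h without exposed replicate 6, where the median change of the 225 genes that rose went from 1.58 to −0.0812, while 28 of the 28 that fell were still lower. Of the comparisons of named genes, 20 were lost under the other size factors, 10 in DESeq2, 8 without the plate term and 70 on 1 plate per time, where there were fewer libraries. The cause of the other moves was not tested. The 6 libraries of few detected genes were all of 24 h lung, so leaving them out could move 4 h counts only through shared steps. These are the filter, size factors, plate term and dispersions of the 1 fit of all lungs, and which of them acted was not tested. No paired analysis was possible because the replicate numbers used here follow the order of the records, the compared groups are different animals and no label pairs them. The 1-plate alternative could give no value for pine needles smolder at either time, where fewer than 2 libraries were left, and there the means and tests over smokes used the other smokes. The flaming against smoldering and fuel-dependent tests there left out pine needles flame as well.

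With DESeq2's size factors in the edgeR fit, 5 of 39 counts moved, in 4 h lung pine flame 3 (1), mean smoke 1 (0), and in 24 h lung red oak flame 644 (253), pine needles flame 0 (1), pine flame 1 (0). Without the filter on low counts, 5 of 39 moved, in 4 h lung pine needles smolder 0 (3), mean smoke 100 (0), and in 24 h lung red oak smolder 0 (1), mean smoke 75 (1), and in heart peat flame 3 (5). With each probe tested alone, 6 of 39 moved, in 4 h lung pine needles smolder 0 (3), fuel-dependent flaming 6 (3), and in 24 h lung red oak smolder 0 (1), peat smolder 0 (1), pine needles flame 0 (1), and in heart peat flame 0 (5). Without the plate term, 6 of 33 moved, in 4 h lung pine needles smolder 0 (3), and in 24 h lung peat smolder 0 (1), pine needles smolder 1 (3), eucalyptus flame 3 (1), mean smoke 2 (1), and between the times saline 8 (0). On 1 plate per time, 9 of 31 moved, in 4 h lung flaming vs smoldering 43 (345), and in 24 h lung red oak smolder 0 (1), peat smolder 0 (1), red oak flame 165 (253), peat flame 6 (10), pine needles flame 0 (1), eucalyptus flame 0 (1), fuel-dependent flaming 514 (1888), and between the times LPS 44 (84).

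Fitting each time alone moved 24 of 30, in 4 h lung peat smolder 1 (0), pine needles smolder 0 (3), pine smolder 1 (0), eucalyptus smolder 2 (0), red oak flame 15 (2), peat flame 1.2e2 (43), pine needles flame 872 (4), pine flame 4 (1), eucalyptus flame 284 (13), LPS 2416 (1298), mean smoke 6 (0), flaming vs smoldering 1564 (345), among smokes 608 (88), and in 24 h lung red oak smolder 0 (1), peat smolder 0 (1), pine needles smolder 1 (3), red oak flame 0 (253), peat flame 3 (10), pine needles flame 0 (1), eucalyptus flame 0 (1), LPS 1142 (1748), mean smoke 0 (1), among smokes 90 (2607), fuel-dependent flaming 0 (1888). Without the libraries of few detected genes, 26 of 33 moved, in 4 h lung peat smolder 1 (0), pine needles smolder 6 (3), pine smolder 1 (0), eucalyptus smolder 7 (0), red oak flame 11 (2), peat flame 1.0e2 (43), pine needles flame 46 (4), pine flame 4 (1), eucalyptus flame 120 (13), LPS 2124 (1298), mean smoke 16 (0), flaming vs smoldering 1260 (345), among smokes 247 (88), fuel-dependent flaming 10 (3), and in 24 h lung red oak smolder 3 (1), red oak flame 0 (253), pine needles flame 1351 (1), eucalyptus flame 11 (1), LPS 2646 (1748), mean smoke 2 (1), flaming vs smoldering 44 (16), among smokes 1500 (2607), fuel-dependent flaming 2 (1888), and between the times smoke 1 (0), LPS 236 (84), saline 45 (0). With the number of detected genes as a covariate, 30 of 39 moved, in 4 h lung peat smolder 1 (0), pine needles smolder 5 (3), pine smolder 3 (0), eucalyptus smolder 68 (0), red oak flame 23 (2), peat flame 501 (43), pine needles flame 1212 (4), pine flame 8 (1), eucalyptus flame 1185 (13), LPS 2174 (1298), mean smoke 522 (0), flaming vs smoldering 1850 (345), among smokes 338 (88), fuel-dependent flaming 10 (3), and in 24 h lung red oak smolder 3 (1), red oak flame 9 (253), peat flame 19 (10), pine needles flame 5 (1), eucalyptus flame 5 (1), LPS 2880 (1748), mean smoke 3 (1), flaming vs smoldering 49 (16), among smokes 140 (2607), fuel-dependent flaming 4 (1888), and between the times smoke 9 (0), LPS 236 (84), saline 635 (0), and in heart peat smolder 0 (480), red oak flame 3 (1344), peat flame 0 (5). With only the compared groups in the heart fit, 2 of 6 moved, in heart peat flame 0 (5), flaming vs smoldering 13 (4). With the DESeq2 test, 29 of 39 moved, in 4 h lung red oak smolder 3 (0), peat smolder 1 (0), pine needles smolder 1 (3), pine smolder 1 (0), eucalyptus smolder 2 (0), red oak flame 11 (2), peat flame 82 (43), pine needles flame 13 (4), pine flame 6 (1), eucalyptus flame 60 (13), mean smoke 8 (0), among smokes 193 (88), fuel-dependent flaming 7 (3), and in 24 h lung red oak smolder 2 (1), peat smolder 2 (1), pine smolder 1 (0), red oak flame 794 (253), peat flame 19 (10), pine needles flame 7 (1), pine flame 2 (0), eucalyptus flame 9 (1), mean smoke 0 (1), flaming vs smoldering 38 (16), and between the times smoke 1 (0), LPS 172 (84), saline 10 (0), and in heart peat smolder 757 (480), peat flame 38 (5), flaming vs smoldering 93 (4).

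Leaving out 1 library at a time moved some counts over these ranges: in 4 h lung red oak smolder 0 to 1 (0), pine needles smolder 0 to 3 (3), eucalyptus smolder 0 to 4 (0), red oak flame 1 to 2 (2), pine needles flame 2 to 45 (4), pine flame 0 to 1 (1), eucalyptus flame 4 to 75 (13), mean smoke 0 to 7 (0). In 24 h lung red oak smolder 0 to 1 (1), peat smolder 0 to 1 (1), pine needles smolder 0 to 3 (3), red oak flame 0 to 459 (253), peat flame 3 to 13 (10), pine needles flame 0 to 1 (1), eucalyptus flame 0 to 3 (1), LPS 986 to 1820 (1748), mean smoke 0 to 2 (1). In the tests between times LPS 19 to 99 (84), saline 0 to 12 (0). In heart peat smolder 141 to 657 (480), red oak flame 644 to 1629 (1344), peat flame 0 to 5 (5).

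The lists called by camera with the preset correlation changed in number with an estimated correlation and with fry, given here in that order. In 4 h lung they were red oak smolder 1 and 0 (8), peat smolder 0 and 0 (13), pine needles smolder 0 and 0 (9), pine smolder 0 and 0 (6), eucalyptus smolder 1 and 0 (11), red oak flame 1 and 1 (12), peat flame 9 and 9 (16), pine needles flame 0 and 0 (4), pine flame 1 and 0 (18), eucalyptus flame 2 and 4 (10), LPS 10 and 13 (17), mean smoke 1 and 1 (13), flaming vs smoldering 0 and 2 (8). In 24 h lung they were red oak smolder 0 and 0 (4), peat smolder 0 and 0 (3), pine needles smolder 0 and 0 (7), pine smolder 0 and 0 (4), eucalyptus smolder 0 and 0 (4), red oak flame 0 and 5 (0), peat flame 1 and 1 (6), pine needles flame 0 and 0 (3), pine flame 1 and 0 (10), eucalyptus flame 0 and 0 (9), LPS 7 and 19 (16), mean smoke 0 and 0 (15), flaming vs smoldering 1 and 0 (7). Between the times they were smoke 0 and 2 (13), LPS 0 and 0 (11), saline 0 and 0 (14). In heart they were red oak smolder 0 and 0 (6), peat smolder 0 and 4 (10), red oak flame 0 and 8 (8), peat flame 0 and 1 (9), flaming vs smoldering 0 and 3 (5), peat vs red oak 0 and 0 (4).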

Other observations

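Cell type markers gave some smaller patterns that the comparisons above leave out. Markers of alveolar macrophages, the resident phagocytes of the lung, were lower by camera with the preset correlation in 6 of 10 smokes at 4 h, with median changes from −1.20 after pine smolder to −0.45 after peat flame. The smallest adjusted p with an estimated correlation was 0.0962, after pine smolder, and 0 of 16 members passed over all genes in any of them. All smokes of a time shared the same 6 saline lungs, and in saline these markers were lower at 24 h than at 4 h (median −0.84, camera with the preset correlation, adjusted p = 0.00629, and 0.505 with an estimated correlation), so part of the pattern may come from the saline lungs, which were not split for these lists. After eucalyptus flame 5 of 16 were lower when adjusted over the list alone. At 24 h the same markers were higher after red oak smolder (median 1.17, with 1 of 16 over all genes, Marco, and 2 adjusted over the list alone, adjusted p = 0.729 with an estimated correlation) and lower after peat flame (median −0.88, 3 of 16 adjusted over the list alone, adjusted p = 0.635 with an estimated correlation).

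Heart muscle markers in 24 h lung were lower by camera in 7 of 10 smokes, most after red oak smolder, where 9 of 15 were lower when adjusted over the list alone (median −1.24, adjusted p = 0.406 with an estimated correlation). The smallest adjusted p with an estimated correlation was 0.29. At 4 h, against other saline lungs, the same markers were higher by camera in 4 of 10 smokes, with a median of 0.90 after eucalyptus flame (smallest adjusted p with an estimated correlation 0.202). Mucous and type 2 response genes, which airway cells raise in allergy, were lower in 4 of 10 smokes at 24 h, and after pine flame the call held with an estimated correlation (median −0.95, 1 of 8 adjusted over the list alone, adjusted p = 0.0457). Genes of red blood cells were higher in 4 of 10 smokes at 24 h, most after pine smolder (median 1.19, 4 of 9 adjusted over the list alone, adjusted p = 0.0719 with an estimated correlation). At 4 h they were lower in 5 of 10, with 0 of 9 passing even adjusted over the list alone (smallest adjusted p with an estimated correlation 0.507), and in saline they were lower at 24 h than at 4 h in 9 of 9 (median −0.60, adjusted p = 0.0386 by camera, and 0.519 with an estimated correlation), so the shared saline lungs may carry part of this pattern. Neutrophil markers were higher in 5 of 10 smokes at 24 h, with 3 of 20 adjusted over the list alone after eucalyptus flame (adjusted p = 0.29 with an estimated correlation).

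The test of random groupings was chosen only after the results were seen. Each comparison was repeated with limma on 100 groupings of its libraries, the real one included, and below are the number of groupings with at least as many called genes, then the real number and the highest other. The shares of groupings were adjusted by Benjamini-Hochberg over the 39 comparisons. By the number of called genes, chance was excluded in 4 h lung for pine needles smolder (1 grouping, 3 genes, highest other 1), peat flame (1, 50, 11), pine needles flame (1, 8, 1), eucalyptus flame (1, 15, 4), LPS (1, 1135, 519), the mean smoke (1, 4, 1), flaming against smoldering (1, 219, 1) and differences among smokes (1, 52, 1). It was excluded in 24 h lung for LPS (1, 1615, 843) and, from 1 gene alone, for pine needles flame (1, 1, 0), and in heart for peat smolder (1, 491, 433) and red oak flame (1, 1349, 275), with an adjusted p of 0.03 for each. The fuel-dependent flaming effect at 4 h (1, 5, 0) had the same adjusted p in this test of groupings. Its groupings mixed all smokes, which also removes differences between fuels and between phases. Chance is therefore not excluded for the fuel dependence itself. These results say only that few groupings gave as many called genes in limma. By genes at unadjusted p under 0.05, as many came in 10 groupings for pine needles smolder, 10 for peat flame, 6 for pine needles flame and 5 for eucalyptus flame at 4 h. It was 10 for the fuel-dependent effect, 4 for the mean smoke and 3 among smokes there, 4 for pine needles flame at 24 h and 2 for peat smolder in heart. For the others it was 1. By that count chance was not excluded for those with 5 or more. The edgeR counts behind the smallest numbers of called genes turned on single animals: the 1 gene of pine needles flame at 24 h was 0 without saline replicate 2, 3, 4 or 5, the 3 of pine needles smolder at 4 h, a group with 5 of 6 lungs on another plate than saline, were 0 without saline replicate 3 or 4, and the mean smoke at 4 h, with 0 in edgeR, gave 7 without saline replicate 1 and 1 without replicate 4. In heart the 480 edgeR genes of peat smolder were 141 without exposed replicate 3. Fewer than 5 groupings gave as many called genes, but the share did not pass after adjustment, for red oak flame (2, 3, 14) and pine flame (2, 1, 1) in 4 h lung (adjusted p = 0.052), peat smolder in 24 h lung (3, 1, 8, adjusted p = 0.0731), and the LPS effect between the times (4, 90, 531) and flaming against smoldering in heart (4, 4, 441, adjusted p = 0.0867 for both).

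Chance could not be excluded in 24 h lung for pine needles smolder (5 groupings, 1 gene, highest other 808), pine smolder (12, 4, 5061), red oak flame (33, 31, 6289), peat flame (10, 5, 6138), flaming against smoldering (7, 20, 7598), differences among smokes (39, 481, 9501) and the fuel-dependent flaming effect (34, 2, 7294), or in heart for peat flame (6, 2, 971). Where the real grouping called 0 genes in limma, each of the 100 groupings called at least as many by definition, so the count tests nothing. In these the highest other was 16 for red oak smolder, 1 for peat smolder, 1 for pine smolder and 2 for eucalyptus smolder in 4 h lung. In 24 h lung it was 2 for red oak smolder, 4889 for eucalyptus smolder, 1541 for pine flame, 6808 for eucalyptus flame and 6013 for the mean smoke. Between the times it was 1 for the smoke effect and 12 for saline, and in heart 704 for red oak smolder and 1 for peat against red oak. Groupings of 24 h lung that called several times as many genes as the real one point to a structure of the samples, and the libraries of few detected genes are such a structure, with as few as 9886 genes against 13948 to 15425 in the other lungs of that group.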
